A study of Mus musculus with 8 samples.

How the data were processed

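Total RNA of sorted Fraction B pro-B cells was extracted, amplified once, labelled with biotin and hybridised to Affymetrix whole-genome mouse arrays, per the labels' protocols. The series was deposited as a single set of values for 8 arrays. The deposited values are on a log2 scale, judged from their range (2.08 to 17.4). The submitters' processing notes name MAS5 and GCRMA without versions, and which of them made these values is not given in the sources used here. The medians per array over all probe sets were 3.44, 3.29, 3.41 and 3.45 in control replicates 1 to 4 and 3.45, 3.50, 3.43 and 3.50 in menin-deficient replicates 1 to 4. Between 36.1% and 36.7% of probe sets sat at the lowest value on each array. Such a floor compresses low values, so folds against it are approximate. No detection calls were used here.

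Groups and replicate numbers were taken from the sample titles. The labels describe separate mice. No 2 arrays held the same values, and correlations over tested genes ran from 0.991 to 0.996 within groups and from 0.985 to 0.991 between groups. The first principal component separated the groups. Dates of hybridisation were not analysed here.

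The table holds 45037 probe sets besides 64 control probe sets of the manufacturer. By the platform annotation, 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. Only those with 1 symbol were named. Entrez identifiers matched 34741 of them to the RefSeq gene table (GRCm38.p6), which gave no other symbol for any and was used for names and neighbourhood only. Probe sets above their own array's 40th percentile on at least 4 of 8 arrays were kept (26790), and the one with the highest mean stood for each gene, which left 11885 genes.

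Menin-deficient and control arrays were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8), without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p values of genes come from that fit unless another is named. In all, 24 gene lists and 15 marker lists were fixed before the data were examined and tested together with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Calls within 10 Mb of Rag1 were compared with calls elsewhere by a two-sided Fisher's exact test. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

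Genes were named by a rule fixed before the data were examined: Men1, the 12 largest rises and 12 largest falls past the threshold with groups that did not overlap, up to 4 members with the lowest p in each list (up to 2 where fewer pass), and a set of B-cell progenitor genes chosen in advance. One gene of that set is not reported here. Text gives a selection of the genes the rule names.

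The fit was tested on simulated data with 200 changed genes among 11885, 4 arrays against 4. It called 47.8% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 100% of those changed by 2, with 6 false calls among 152. Genes were simulated independently, and the real comparison called 2536 genes, so these shares need not hold for it.

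Alternatives fixed before the data were examined were another quantile normalization, median centring, no filter and a 60th percentile filter, the mean of a gene's probe sets, every probe set on its own, trended and robust eBayes, array weights, the replicate number as a block, sex as a covariate, a threshold of 0.10, windows of 5 and 20 Mb, and leaving out each array in turn. Added after seeing the data were the exclusion of _x_at and _s_at probe sets (those that can match several transcripts), centring on the median tested gene, female mice alone, and leaving out genes near Rag1. A pseudocount did not apply to log2 values.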

Results

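Menin, the product of Men1, is a chromatin-associated protein that joins the histone methyltransferase MLL (Kmt2a) at target genes. The comparison asked which genes depend on menin in early B-cell progenitors of mouse bone marrow. RNA came from Fraction B pro-B cells, sorted as B220+ CD43+ HSA+ BP-1- cells. Of the 8 mice, 4 carried floxed Men1 without Cre (control) and 4 carried floxed Men1 with Rag1-cre (menin-deficient), at about 2 to 3 weeks of age. Each mouse gave 1 expression array with log2 values for 45037 probe sets. Cre was carried by every menin-deficient mouse and by no control, so effects of Cre and of menin loss cannot be told apart here. The number of arrays, 4 in each group, limits the precision. By Xist and Eif2s3y levels, 1 control and 2 menin-deficient mice were male.

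Men1 itself fell. Its brightest probe set went from 9.54 ± 0.256 in control to 8.15 ± 0.278 in menin-deficient arrays (mean ± SD of log2 values, n = 4 each), a log2 difference of -1.39 (SE 0.18, limma adjusted p = 0.00391). This is 2.62-fold lower, and the groups did not overlap. The second probe set differed by -1.38 and the dimmest by -0.37. Where these probe sets lie relative to the deleted part of Men1 is not given in the sources used here, so they may not check the deletion itself. In the 5 female mice alone (3 control, 2 menin-deficient) the difference was -1.27 with an adjusted p of 0.0699.

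Among 11885 genes tested, 2536 changed at an adjusted p under 0.05, 1922 higher and 614 lower in menin-deficient cells, and 397 changed at least 2-fold. The largest rises were in Rps6ka6, a ribosomal S6 kinase (37.4-fold), Ndn, the imprinted MAGE-family gene necdin (33.2-fold), and Dgkeos (19.8-fold). Wscd1, Bex2, Cda, Mpzl2, Clgn, Nr1d1, Lmcd1, Clic6 and Iigp1 rose by 6.89-fold to 13.5-fold. Rps6ka6, Wscd1, Cda, Mpzl2 and Lmcd1 had control means of 2.55, 2.24, 2.89, 2.10 and 2.75, close to the lowest value of the table (2.08), so their folds are set against background and are approximate. Ndn went from 4.80 ± 0.532 to 9.85 ± 0.192 (log2, SD, n = 4 each), and its 4 other probe sets rose too, by 13.2-fold to 51.9-fold. Cda encodes cytidine deaminase and Nr1d1 the clock repressor REV-ERB alpha.

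The largest fall was in Eya1, a transcriptional co-activator and phosphatase, which was 17.1-fold lower (log2 difference -4.10, SE 0.21, adjusted p = 0.000363). An immunoglobulin kappa variable segment was 8.94-fold lower on average, with 3 of 4 menin-deficient arrays near background, and Jchain, the joining chain of secreted IgM and IgA, 7.22-fold lower. Sytl4, Prkaca, Rapgef3, Mir99ahg, Adgrl4, Kdm4a, Abtb2, Atp7a and Col5a3 fell by 3.48-fold to 5.36-fold. The fold of Mir99ahg is approximate too, since its menin-deficient mean was 2.51. The fall of Prkaca rests on 1 probe set of a kind that can match several transcripts. Its other probe set differed by 0.022 at a low level (4.15 in control). For Abtb2, too, the other probe set did not fall.

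The excess of rises depended on scaling. The median tested gene was 0.11 higher in menin-deficient arrays, and centring each array on its median tested gene removed 0.13 of log2 difference from every gene. Relative to that centre 911 genes were higher and 971 lower, so 48.4% of calls were rises against 75.8% as deposited. Of the calls above, 1525 kept their direction and their call. Every one of the 24 genes named for the largest rises and falls stayed past the threshold after centring. They were picked for large differences, so a shift of 0.13 could hardly lose them. Under other alternatives some calls were lost: Atp7a under 7 of 23, Col5a3 under 5, Adgrl4 under 4, and the rest under fewer or none. The count of changed genes was 1622 without control replicate 1 and 1413 without menin-deficient replicate 2.

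Homeobox and leukaemia genes that menin and MLL are known to regulate fell in part. Of 19 tested members, 7 fell, 1 rose and 11 did not pass. Adjusted over the list alone, 8 fell and 2 rose, and after centring 8 were lower and 1 higher. Besides Eya1, Hoxa9 fell 3.17-fold (12.6 ± 0.375 to 11.0 ± 0.329, log2, SD, n = 4 each), Hoxa5 fell 2.46-fold and Meis1, the Hox cofactor, fell 2.28-fold. Zfp521 rose 3.25-fold. The list was called lower by camera (adjusted p = 0.00458 at a preset correlation), but not with an estimated correlation (adjusted p = 0.279). Among subunits of the MLL and menin complexes, 2 of 23 rose and 2 fell, Men1 among the latter (1 and 4 after centring). Kmt2a differed by 0.15 (adjusted p = 0.429).

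**Figure D1:**
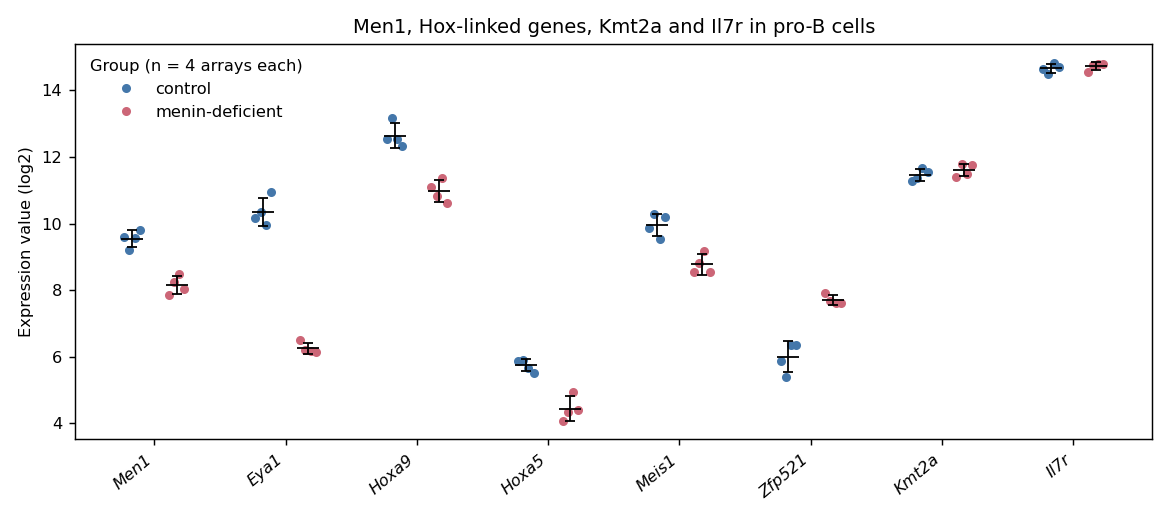
Log2 expression values (vertical axis) of 8 genes on the 4 control and 4 menin-deficient arrays; each point is 1 array, and bars give the mean ± SD. Eya1 lay at 10.3 in control and 6.25 in menin-deficient arrays on average, while Il7r differed by 0.06.

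Genes of B-lineage identity went both ways. Of 34 tested B-lineage transcription factors, 3 rose and 4 fell, and after centring 1 was higher and 7 lower. Lef1 rose 1.49-fold, Zeb2 fell 2.03-fold and Ikzf3 fell 1.83-fold. On their brightest probe sets Ebf1 differed by 0.06, Pax5 by -0.07, Tcf3 by 0.27 and Foxo1 by -0.05, none past the threshold. With every probe set tested on its own, another Ebf1 probe set was lower (-0.75, adjusted p = 0.0162), the other Tcf3 probe sets were higher (0.48 and 0.63, adjusted p = 0.0192 and 0.0178), and another of Foxo1 differed by 0.46 (adjusted p = 0.0646). The list was not called by camera (adjusted p = 0.199), but was called under 2 of 23 alternatives, those that averaged or separately tested the probe sets. Of 30 pre-B-cell receptor and B-cell receptor signalling genes, 6 rose and 0 fell, among them Prkcd (log2 difference 0.59, but -0.019 on its other probe set) and Fyn (1.56-fold). After centring 2 of these genes were higher and 1 lower. Igll1, a surrogate light chain gene, rose 1.30-fold on a probe set that can match several transcripts, and its other probe set lay near background (2.42 and 2.30). That call was lost under 14 of 23 alternatives, centring on the median tested gene among them. Vpreb1 differed by 0.02, Cd79a by 0.18 and Ighm by 0.14. In V(D)J recombination and end joining, 4 of 18 rose and 2 fell (2 and 2 after centring). The fall of Trp53bp1 (-0.73) is doubtful, since another of its probe sets was higher (0.44, adjusted p = 0.0117 with every probe set tested on its own). Dntt rose 1.28-fold on its brightest probe set, but its other probe sets differed by 0.23 and -0.44, not past the threshold on their own. With the mean of its probe sets Dntt was not called (adjusted p = 0.612). Rag1, for which the Cre carrier is named, fell 1.21-fold, a call lost under 10 of 23 alternatives. Rag2 differed by 0.33 (adjusted p = 0.331).

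The receptor for IL-7, the main growth factor of pro-B cells, did not differ detectably (Il7r 0.06, adjusted p = 0.663). Of 22 genes of IL-7 receptor and STAT5 signalling, 6 rose and 3 fell (4 and 4 after centring). The fall of Pim3 rests on an _x_at probe set, and its other probe set differed by 0.49. For Bcl2l1, which fell too, the other probe set differed by 0.50 at a low level (3.44 in control). Neither of these passed the threshold on its own. Socs2 rose 2.60-fold and Stat5a 1.74-fold, and Crlf2 fell 1.94-fold. The CDK inhibitors split: of 5 tested, Cdkn1c rose 2.14-fold, Cdkn1a rose 2.10-fold and Cdkn1b fell 1.55-fold on its brightest probe set, while its other probe set differed by 0.056. Cdkn2c differed by 0.09 (adjusted p = 0.494). DNA replication genes changed in 5 of 39 cases (2 higher, 3 lower) and mitosis genes in 5 of 39 (1 higher, 4 lower, and 1 and 2 adjusted over the list alone). After centring 0 and 4 replication genes and 1 and 5 mitosis genes were higher and lower. The falls of Mcm5, Ccne1 and Cdc20 rest on _x_at probe sets, and without _x_at and _s_at probe sets these genes differed by 0.16, 0.25 and 0.24, none past the threshold. Probe sets of Kif2c disagreed: a dim one fell as well (-1.34, adjusted p = 0.00117 with every probe set tested on its own) and 2 others differed by 0.24 and 0.021. Myc differed by -0.06, Bcl2 by -0.18, Kit by 0.28 and Flt3 by 0.66, none past the threshold on its brightest probe set. The sort markers Cd24a, Spn, Ptprc and Enpep differed by -0.06, 0.01, -0.13 and 0.29 on theirs, none past it either. With every probe set tested on its own, 1 of Bcl2 (-0.50, adjusted p = 0.0120) and 1 of Ptprc (-0.72, adjusted p = 0.0400) were lower.

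Many interferon-stimulated genes rose. Of 39 tested, 22 rose, 0 fell and 17 did not pass, and adjusted over the list alone 24 rose and 1 fell. Iigp1, an interferon-inducible GTPase, rose 6.89-fold, Oas1a 2.51-fold, Isg20 2.01-fold and Gbp6 1.94-fold. Camera called the list higher (adjusted p = 0.000144 at a preset correlation), but not with an estimated correlation (adjusted p = 0.936). After centring 14 members were higher and 1 lower. The count was 14 without control replicate 1 and 14 without control replicate 4, and 11 without menin-deficient replicate 2 and 13 without menin-deficient replicate 3. In female mice alone it was 2, with a median difference of the list of 0.48 there against 0.58 in all mice. Camera at the preset correlation called the list under all 23 alternatives.

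Some markers of other blood cells rose. Of 9 tested T cell markers (15 are on the array) 5 rose, led by Thy1 (6.26-fold) and Lat (3.39-fold). Of 12 NK cell markers 3 rose, among them Ncr1 (2.66-fold) and Nkg7 (1.87-fold). Ncr1 and the T cell marker Cd3g, which rose too, were dim in control arrays (3.20 and 3.95), so such folds are approximate. The mean of the NK list was 7.12 in menin-deficient replicate 3, 6.14 to 6.18 in the other menin-deficient arrays and 5.39 to 5.78 in control arrays. Of 20 monocyte and macrophage markers 5 rose, including Ccr2 (1.52-fold). Of 13 plasmacytoid dendritic cell markers 4 rose: Ccr9 (3.14-fold), Irf7 (2.14-fold), and Dntt and Atp1b1, both already high in control arrays (15.4 and 14.9). No marker of these lists fell, after centring 4, 3, 3 and 3 markers were higher, and 21.3% of all tested genes changed. Camera called none of the T cell, NK cell, monocyte and plasmacytoid lists (adjusted p = 0.0744, 0.199, 0.443 and 0.276). The T cell and NK cell lists were called under 6 and 3 of 23 alternatives, centring on the median tested gene among them, and the monocyte list under 1, female mice alone. Of 10 plasma cell markers 3 fell, Jchain, Sdc1 (2.24-fold) and Iglv1 (1.97-fold), and Mzb1 rose (3 lower and 0 higher after centring). The fall of Iglv1 rests on an _x_at probe set, and its other probe sets differed by -0.41 and -0.12, not past the threshold.

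**Figure D2:**
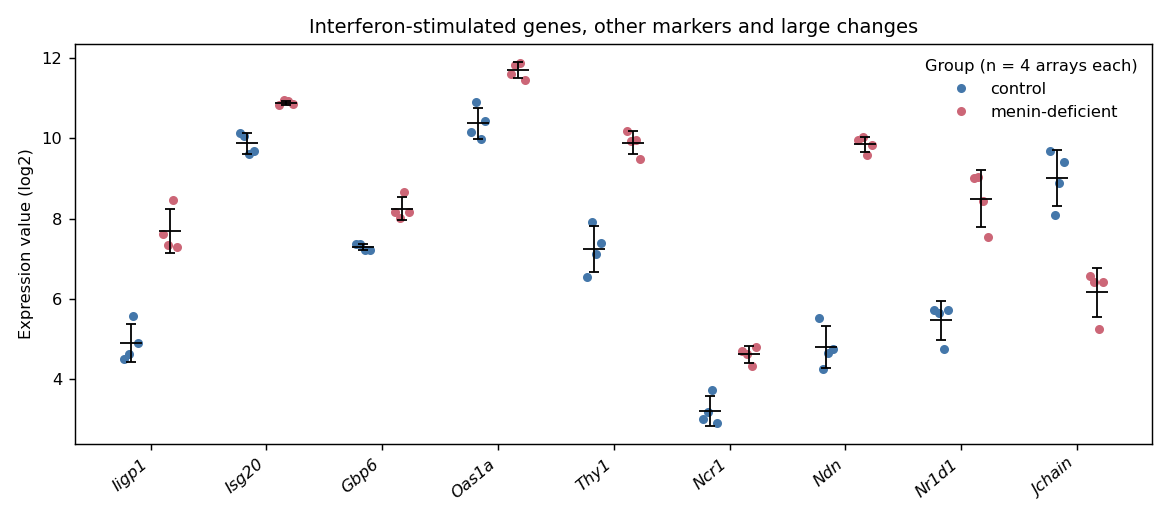
Log2 expression values (vertical axis) of 4 interferon-stimulated genes, Thy1, Ncr1, Ndn, Nr1d1 and Jchain; each point is 1 array, and bars give the mean ± SD of the 4 arrays of a group. Thy1 averaged 7.24 in control and 9.89 in menin-deficient arrays.

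The Cre carrier is named for Rag1 on chromosome 2, so genes near it were examined as a group. Of 62 tested genes within 10 Mb of Rag1 (neighbours taken from GRCm38.p6), 26 changed, 17 higher and 9 lower, against 21.3% of genes elsewhere (odds ratio 2.67, 95% interval 1.55 to 4.56, two-sided Fisher's exact p = 0.000256). Among them Abtb2 and Cd44 fell, Cat, encoding catalase, fell 1.43-fold on its brightest probe set but differed by 0.42 on the other (adjusted p = 0.107 with every probe set tested on its own), and Ext2 rose 1.62-fold. Depdc7 (6.48-fold) and Lgr4 (4.37-fold), named after their values were seen, rose most. The odds ratio was 3.94 within 5 Mb and 1.14 within 20 Mb (Fisher's exact p = 0.471), and without control replicate 1 it was 1.52 (Fisher's exact p = 0.194).

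**Figure D3:**
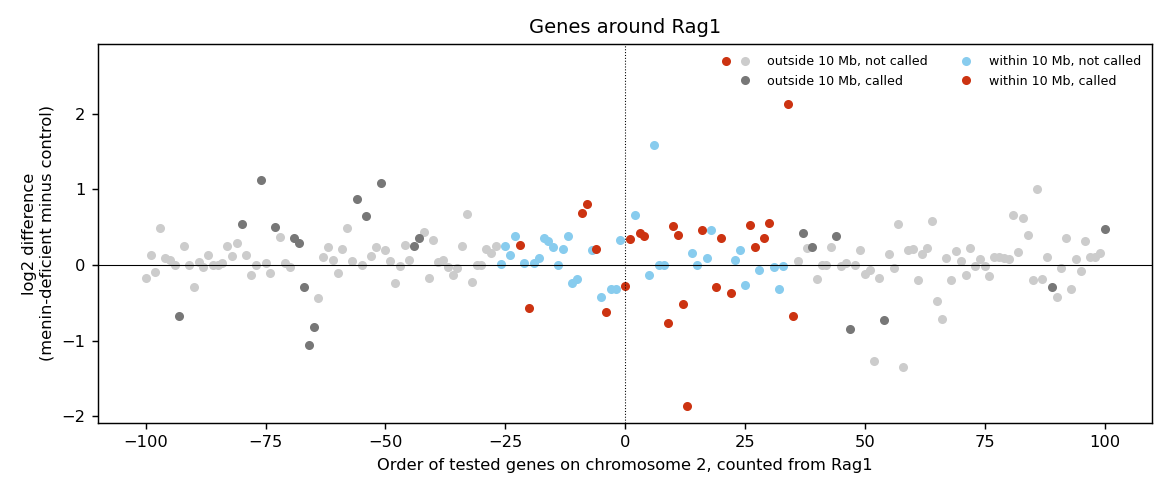
Log2 difference, menin-deficient minus control (vertical axis), of tested genes on chromosome 2 in their order from Rag1 (horizontal axis, number of genes); colours give distance within or beyond 10 Mb and whether the gene passed the threshold. Of the 62 genes within 10 Mb, 26 passed it.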

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

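All tests in this part were chosen after the results were seen, except the count of splits for all changed genes and for lists and the Fisher's exact test around Rag1.

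Of the 35 splits of the 8 arrays into 4 and 4, only the real one (1 of 35) called as many genes as the 2536 found, and the highest other split called 4. The same held for the 1922 rises and the 614 falls (1 of 35 each, highest other 3) and for genes changed at least 2-fold (1 of 35, 397 against 4). This share is the smallest that 35 splits allow (0.0286), so it argues against chance for all changed genes without excluding it. The counts of rises, falls and 2-fold changes add no separate evidence, since every other split mixes the genotypes and called few genes or none. For the gene lists chance is not argued against: 30 of the 35 splits had at least 2 lists called by camera at the preset correlation, and the highest other had 12. The interferon list was called in 14 splits and the Hox list in 5. For the 22 higher interferon genes and the 26 called genes near Rag1 the splits decide nothing: only the real one (1 of 35) reached either count, but no other called over 4 genes in all.

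Falls were found on probe sets that can match several transcripts more often than on others. Of 481 genes represented by an _x_at probe set 91 fell, 18.9% against 3.77% for plain _at sets. Other probe sets of 81 of these genes had a median difference of 0.087 (bootstrap interval 0.02 to 0.13) where the _x_at sets had -0.64, which argues against a fall of the named genes and for hybridisation shared with other transcripts or repeats. Other, dimmer probe sets also understate falls called on plain _at sets (-0.14 against -0.49). Control probe sets for B1 and B2 repeats were lower by -0.75 and -0.65 (exact permutation p = 0.0286 each, the smallest possible, 0.0667 adjusted over 7 measures), and within groups B1 followed these _x_at sets (Pearson r = 0.73, exact permutation p = 0.0174, 0.0347 adjusted over 2 relations, Spearman 0.62, p = 0.0677, n = 8), with r = 0.46 without the 2 farthest arrays, so that a common factor may lie behind both.

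For the interferon genes, unequal sexes and a shift of all genes are argued against as the whole cause: 21 of 22 stayed past the threshold with sex in the model and 14 after centring. Admixed NK cells and plasmacytoid dendritic cells, which B220+ CD43+ cells could include, stay open, although the sort also took HSA+ BP-1- cells and would remove those without HSA. The NK list did not track the interferon genes within groups detectably (Pearson r = 0.20, exact permutation p = 0.745, Spearman -0.05, p = 0.938, n = 8), with r = 0.65 without the 2 farthest arrays, and the 11 plasmacytoid markers had a median difference of 0.29 (bootstrap interval -0.01 to 1.13) against 0.91 for the interferon genes. That median cannot decide, since Dntt, Atp1b1 and Tcf4 were high in control arrays already (15.4, 14.9 and 12.8) and Tlr9 lay near the floor. Of the other markers, Siglech, an abundant marker of that cell, differed by 1.17 (adjusted p = 0.0621), Tlr7 by 1.13 and Ccr9 by 1.65. Klk1, Cox6a2, Pltp and Cd300c2 differed by -0.093, -0.35, 0.083 and 0.21. A response of menin-deficient cells themselves stays open too, as untested, and an effect of Cre itself cannot be told apart from it.

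Calls within 10 Mb of Rag1 met the test set in advance for DNA linked to the Cre carrier (odds ratio 2.67). Of 11594 equally wide windows centred on other genes and holding at least 20 tested genes, 6 (0.0518%) held as large a share as the 41.9% around Rag1. A window on chromosome 3 held 43.5% (10 of 23). Such clustering was thus rare but not absent elsewhere, and the windows overlap. Without _x_at and _s_at probe sets the odds ratio was 2.57, which argues against shared probe sets as its source. Genes within 10 Mb of Men1 were called more often as well (odds ratio 1.60, 95% interval 1.16 to 2.17, Fisher's exact p = 0.0034). The upper bound lay under the odds ratio around Rag1, but the intervals overlapped. Both groups carried floxed Men1, so the design gives no reason for different DNA there. The test around Men1 cannot decide whether both excesses have the same source, since the outcomes set for and against this were both met. Linked DNA stays 1 open explanation of the excess around Rag1. Strain variants were not analysed here.

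Single arrays stood apart from the other 3 of their group for 27 of 167 named genes. Both groups of each gene were open to this flag and chance flags about 1 in 20 groups, so many of these flags are expected by chance. In Wscd1, Lmcd1 and Cxcl12 the other 3 arrays held the same value, close to the lowest of the table, so the flag means little there. Control replicate 3 stood apart in Wscd1 (2.27), Nr1d1 (4.75), Kdm4a (7.25), Casp6 (11.6), H2-K1 (14.5), Cpa3 (8.50), Igll1 (15.4) and Cd24a (16.3), and as the only male control in Xist (2.66) and Eif2s3y (14.1). Control replicate 1 did in Rpl14 (12.2), Sac3d1 (9.99) and Cxcl12 (2.08), control replicate 2 in Col5a3 (8.24) and Pim3 (13.3), and control replicate 4 in Lmcd1 (2.86). Menin-deficient replicate 1 did in Eya1 (6.50), Bcl2l1 (10.3) and Il7r (14.5), replicate 2 in an immunoglobulin kappa variable segment (4.42), Sytl4 (6.69) and Poll (9.88), replicate 3 in Jchain (5.25), Zeb2 (11.6) and Enpep (10.4), and replicate 4 in Egr3 (7.63) and Fdps (11.0). Among 4590 kept probe sets without a single gene name, 208 were higher and 243 lower in menin-deficient arrays.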

How the results depend on the processing

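The exclusion of _x_at and _s_at probe sets, centring on the median tested gene, female mice alone and leaving out genes near Rag1 were chosen after seeing the data. The cause of the changes below was not tested, except that fewer arrays or more tests are part of some settings by construction. Men1 stayed lower and past the threshold under all alternatives but female mice alone (-1.27, adjusted p = 0.0699).

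Rises numbered 1082 with median centring over all probe sets and 911 with centring on the median tested gene, where falls numbered 971. Without a filter 1673 genes changed and 1257 rose. Probe sets on their own gave 3808 changes, 1305 falls and 699 in the count of genes changed at least 2-fold. Female mice alone gave 639 changes, 498 rises, 141 falls and 176 at least 2-fold. Leaving out 1 array gave 1413 to 2269 changes, 1045 to 1703 rises and 368 to 566 falls, lowest without menin-deficient replicate 2, and 1622 changes and 1202 rises without control replicate 1.

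Lists called numbered 2 in the main setting, 5 with median centring, 6 with the mean of probe sets, 7 with probe sets on their own, 4 with centring on the median tested gene, 4 in female mice, 13 with fry, which does not compare a list with other genes, and 0 with correlation estimated per list. The odds ratio around Rag1 was 1.14 within 20 Mb and 1.52 to 2.68 when 1 array was left out, lowest and not past the threshold without control replicate 1.

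With the replicate number as a block, 1328 genes changed, 984 higher and 344 lower, and the odds ratio around Rag1 was 1.53 (Fisher's exact p = 0.223). The numbers do not pair the samples: deviations of arrays with the same number correlated at -0.107, -0.313, -0.171 and 0.0459, and 0 of 8 arrays correlated best with their own number.

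With the mean of probe sets Trp53bp1 (0.010), Pml (-0.17) and Bcl2l1 (0.044) changed sign. Without _x_at and _s_at probe sets so did Prkaca (0.022), Pim3 (0.49), Ccne1 (0.25), Mcm5 (0.16), Cdc20 (0.24), Kif2c (0.24), Pigq (0.076), Cstf3 (-0.17) and Igll1 (-0.12, on a probe set near background that gives no direction), and Foxo1 was higher (0.46). Of 139 called named genes, 27 kept direction and call under every alternative that tested them, Men1 not counted. Low signal limits genes near the floor.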

Other observations

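The tests of lists in this part were planned, and the test on clock genes was chosen after the result was seen. Of 20 sterol synthesis genes 5 rose and 0 fell (10 and 0 adjusted over the list alone, 3 and 0 after centring), among them Fdps, farnesyl diphosphate synthase (1.76-fold), and Msmo1 (1.54-fold), and the list was not called by camera (adjusted p = 0.199), but was under 3 of 23 alternatives. Of 28 unfolded protein response genes 7 rose and 1 fell, with Pdia6 1.53-fold higher and Dnajb9 1.36-fold lower, but after centring 1 was higher and 2 lower. Of 19 antigen presentation genes 4 rose, including H2-Oa (1.52-fold), and 1 did after centring. Of 25 p53 targets 6 rose, including Cdkn1a, and after centring 3 were higher and 2 lower. Of 28 apoptosis regulators 3 rose and 2 fell (2 and 5 after centring), with Casp6 1.74-fold higher and Bak1 1.80-fold lower. Of 20 adhesion and homing genes 6 rose and 3 fell (3 and 3 after centring), and Cd9 was 2.18-fold higher. Oxidative phosphorylation genes went both ways, 14 higher and 9 lower of 52, and 2 and 11 after centring. Ribosomal protein genes did too, 5 higher and 7 lower of 44, and 0 and 7 after centring.

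Of 36 immediate-early and stress genes 2 rose and 4 fell, and 2 and 6 after centring (adjusted p = 0.0538 by camera, called under 6 of 23 alternatives). Egr3 fell 2.30-fold and Egr1 1.53-fold, while Ier2 rose 1.63-fold and Ier5 1.59-fold. Of 22 NF-kB targets 2 rose and 3 fell (1 and 5 after centring), Nfkbia among the falls (1.44-fold). Of 29 glycolysis and hypoxia genes 2 rose and 4 fell (1 and 6 after centring). These falls include Pigq, which the fixed list did not name and which was matched to it through a gene synonym. They also include Slc2a1, of which another probe set was higher (0.38, adjusted p = 0.00428 with every probe set tested on its own). For Higd1a, the other probe sets differed by -0.05 and 0.12. Of 40 ribosome biogenesis and MYC targets 2 rose and 2 fell (1 and 2 after centring). The fixed list of genes near Rag1 had 11 higher and 6 lower of 46, which turned to 4 and 8 after centring. That near Men1 had 5 higher and 5 lower of 22, and 2 and 6 after centring. Of 12 early progenitor markers 2 rose, of 13 stem cell markers 1 fell, and of 11 later pre-B markers 1 fell (Il2ra, 1.83-fold). Those counts were 2 higher, 1 lower and 2 lower after centring. Of 17 mature B-cell markers 1 rose (Cd37, 1.39-fold), but after centring 0 were higher and 3 lower. Of 17 neutrophil, 11 stromal and 4 sex markers 0 passed the threshold in limma. Of 20 erythroid markers 2 rose, of 10 megakaryocyte markers 1 rose and of 10 mast cell, basophil and eosinophil markers 2 rose, with 0, 1 and 2 higher after centring. The neutrophil list was called by camera under 1 of 23 alternatives, female mice alone. Medians and means differed in sign for MLL complex subunits (0.02 and -0.06), NF-kB targets (0.04 and -0.04), ribosomal proteins (0.08 and -0.03), later pre-B markers (0.02 and -0.14) and plasma cell markers (0.09 and -0.32).

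A candidate explanation for the higher Nr1d1 is another time of day at collection. Other clock output genes, Dbp, Tef, Nr1d2, Per3 and Ciart, had a median difference of -0.056, which argues against a shift of them all by the size seen in Nr1d1. Per3 alone rose past the threshold (0.55, adjusted p = 0.00868).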
